A study of Mus musculus with 23 samples.

How the data were processed

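Poly(A)-selected, strand-specific RNA sequencing libraries of whole spinal cord lysate were compared between PS19 mice, which carry a human tau transgene, and littermate controls. The 23 samples formed 4 groups: 7 PS19 and 6 control animals at 9 months, and 5 PS19 and 5 control animals at 4 months. The labels gave no sex, batch or replicate number, so replicates were numbered in order and no animals were paired.

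The values are a signal per repeat subfamily, deposited by the authors as read numbers divided by a size factor for each sample. The submitters' processing notes name Trimmomatic, STAR, DESeq2 and the mouse build mm10, without versions. The program that assigned reads to repeats, the repeat annotation and the treatment of reads that map to many copies are not given in the sources used here. It is also not given whether the 2 ages were scaled together, or from which features the size factors came. Subfamilies of a family share sequence, so reads could be divided between near-identical subfamilies, and values of related subfamilies are not independent. The table used here had 1135 rows, each a repeat subfamily with its family and class. All 23 sample columns matched a sample title, and 0 columns were left unused.

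Each column consisted of whole multiples of the value of a single read, within 0.1 percent of a read for 100 percent of values. This gave the reads behind each value. Repeat reads per sample ranged from 338090 to 2168280. Sample pairs of a group differed by more than sampling noise, the lowest chi-square per degree of freedom being 3.73, so every sample counted as a replicate.

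For each comparison, log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), with a mean per group over all 23 samples. Subfamilies with a mean value of at least 10 over all samples were tested, which left 920 and removed 215. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low subfamilies. A fit of the samples of each age alone had been planned as an alternative. It was given equal room for the 9-month comparison only after both counts had been seen, because the 4-month samples were far more variable. Counts from both fits are given side by side.

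Subfamilies were named by a rule fixed before the data were examined: the 8 higher and 8 lower with the smallest p among those past the threshold, the 4 higher and 4 lower with the largest fold change at a mean value of at least 50, and for the age comparisons the 4 higher and 4 lower with the smallest p. The rule was applied to both fits at 9 months. The 43 gene lists fixed beforehand had 0 members in the table, which covers repeats. The gene lists, the transgene check, a sex covariate from Xist and the position of called genes were therefore not analysed here. Repeat families, classes and name groups with at least 5 tested members were used in their place and were chosen after the table was seen. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Sums per sample were compared with two-sided exact permutation tests within an age. The interaction of the named subfamilies was tested with 100000 two-sided permutations of genotype within each age.

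Alternatives were other pseudocounts (0.5 and 5), no filter and a filter at 50, quantile and TMM scaling within repeats, sample weights, robust and untrended variance, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a threshold of 0.01, and leaving out each sample. With all samples, edgeR called 1 subfamily and DESeq2 called 2 at 9 months. On the 9-month samples alone, edgeR called 24 and DESeq2 called 45.

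The fits were tested on simulated reads with 200 subfamilies changed by known folds, drawn from the means and size factors of the real samples. The spread of each subfamily was estimated from the 9-month samples and used at both ages, and subfamilies were drawn independently. The spread within the sets of real 4-month samples was not used, so recovery at 4 months may be overstated. For the 9-month comparison, the fit of all samples recovered 9.38 percent of 64 changes of 2-fold and 76.7 percent of 73 changes of 4-fold among 910 subfamilies. The fit of 9-month samples alone recovered 75 percent and 87.7 percent, and called 7 of 715 unchanged subfamilies. For the 4-month comparison, the fit of all samples recovered 3.12 percent of 64 changes of 2-fold and 66.7 percent of 72 changes of 4-fold among 909 subfamilies. The fit of 4-month samples alone recovered 0 percent of either. With a term for the 2 sets of 4-month samples, it recovered 34.4 percent of 61 changes of 1.5-fold, 68.8 percent of those of 2-fold and 97.2 percent of those of 4-fold, and called 4 of 712 unchanged subfamilies.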

Results

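RNA reads assigned to transposable elements and other repeats were compared in spinal cord of PS19 mice, a tauopathy model with a human tau transgene, and of littermate controls at 4 and 9 months. Whether such reads came from transcripts of the elements themselves or from repeat sequence in other RNA was not tested. At 9 months, SINE elements made up 46.4% ± 0.92 (SD, n = 13) of the repeat signal, LTR elements, the remains of endogenous retroviruses, 28.7% ± 1.19 and LINE elements 17.2% ± 0.55. Repeat reads per sample ranged from 338090 to 590194 at 9 months and from 529522 to 2168280 at 4 months.

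The 4-month samples fell into sets of very different repeat signal. Replicates 1 to 3 of both genotypes had totals of 1494940 to 2459740 normalized reads. Replicates 4 and 5 of both genotypes had 471178 to 779835, and all 9-month samples had 370990 to 539759. Of 920 tested subfamilies, 914 were higher in replicates 1 to 3 of the 4-month animals. The sets were defined after the totals were seen and held 3 and 2 animals of each genotype. They also followed the sample numbers, as all of replicates 1 to 3 carried lower numbers than all of replicates 4 and 5. The labels do not say what these numbers stand for.

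**Figure D1:**
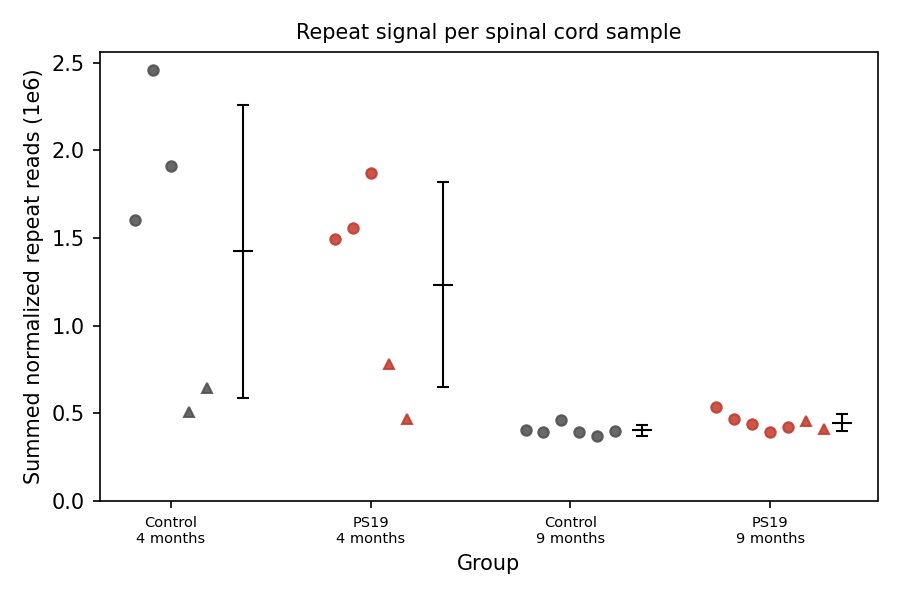
Summed normalized repeat reads per sample (vertical axis, in units of 1e6) for the 4 groups, with grey for control and red for PS19 and bars for mean and SD. Triangles mark replicates 4 and 5 at 4 months and PS19 replicates 6 and 7 at 9 months; at 4 months, replicates 1 to 3 lie at 1494940 or above and the triangles at 779835 or below.

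The first comparison asked which repeats differ between PS19 and control at 9 months. RLTR45-int, the internal part of an ERVK endogenous retrovirus, was higher in PS19, at 268 ± 137 normalized reads (SD, n = 7) against 66.0 ± 17.4 (SD, n = 6), and each of the 7 PS19 animals lay above every control. Its log2 fold change was 1.89 (SE 0.35), with a limma adjusted p of 0.00699. In the limma fit of all samples it was the 1 subfamily of 920 past the threshold. In that fit 28 had an unadjusted p under 0.05, fewer than the 5 percent of the 920 that chance alone gives. The median log2 fold change of all subfamilies was 0.19, so that changes are to be read against this general shift. The shift was 0.01 when samples were scaled within repeats.

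In the limma fit of the 9-month samples alone, 31 subfamilies passed the threshold, 28 higher and 3 lower in PS19. MMERGLN-int, an ERV1 internal part, was at 341 ± 63.6 (SD, n = 7) against 157.7 ± 61.0 (SD, n = 6), a log2 fold change of 1.17 (adjusted p 0.000475). MuLV-int, from murine leukemia virus-type elements, was at 402 ± 118 against 207 ± 52.4 (log2 fold change 0.93, adjusted p 0.00712). IAPEz-int, the internal part of intracisternal A particles, was at 19694 ± 4809 against 12276 ± 2296 (log2 fold change 0.66, adjusted p 0.0144). ORR1A1-int (0.80), RLTR28 (0.70), MERV1_I-int (0.90), RLTR24 (0.79), RLTR30D2_MM (1.06) and RLTR16C_MM (1.28) were the other named subfamilies that rose, given as log2 fold changes. RLTR16C_MM had few reads at this age, with 12.6 normalized reads in control replicate 3 and 3.02 to 5.69 in the other controls. RMER17C2 (-0.51), LTR50 (-0.55) and LTR81 (-0.41) fell, but 0 lower calls were left with no filter and with no variance trend. These 3 lay at the 95.2, 98.3 and 99.7 percentile of the difference between 9 and 4 months, and LTR81, at 9.05 ± 5.77 at 4 months (SD, n = 10) and 524 ± 90.8 at 9 months (SD, n = 13), is among the 9 subfamilies far higher at 9 months, for which different counting at the 2 ages cannot be told apart from age. After scaling within repeats, 8 of the 28 higher subfamilies passed, among 8 higher and 7 lower calls in all, while leaving out a single animal gave between 7 and 78 calls. Under that scaling MuLV-int (log2 fold change 0.75, adjusted p 0.0672), IAPEz-int (0.48, 0.131), RLTR24 (0.61, 0.0694) and RLTR16C_MM (1.13, 0.0648) no longer passed, and the other named subfamilies did. Over the 13 fits that each left out 1 animal, the call was lost in 11 for RLTR16C_MM, 8 for LTR81, 5 for RLTR30D2_MM, 4 for RLTR24 and 1 each for IAPEz-int, LTR50 and RMER17C2. PS19 replicates 1 to 5 carried lower sample numbers than every control, and with PS19 replicates 6 and 7 alone against the 6 controls 6 subfamilies passed.

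**Figure D2:**
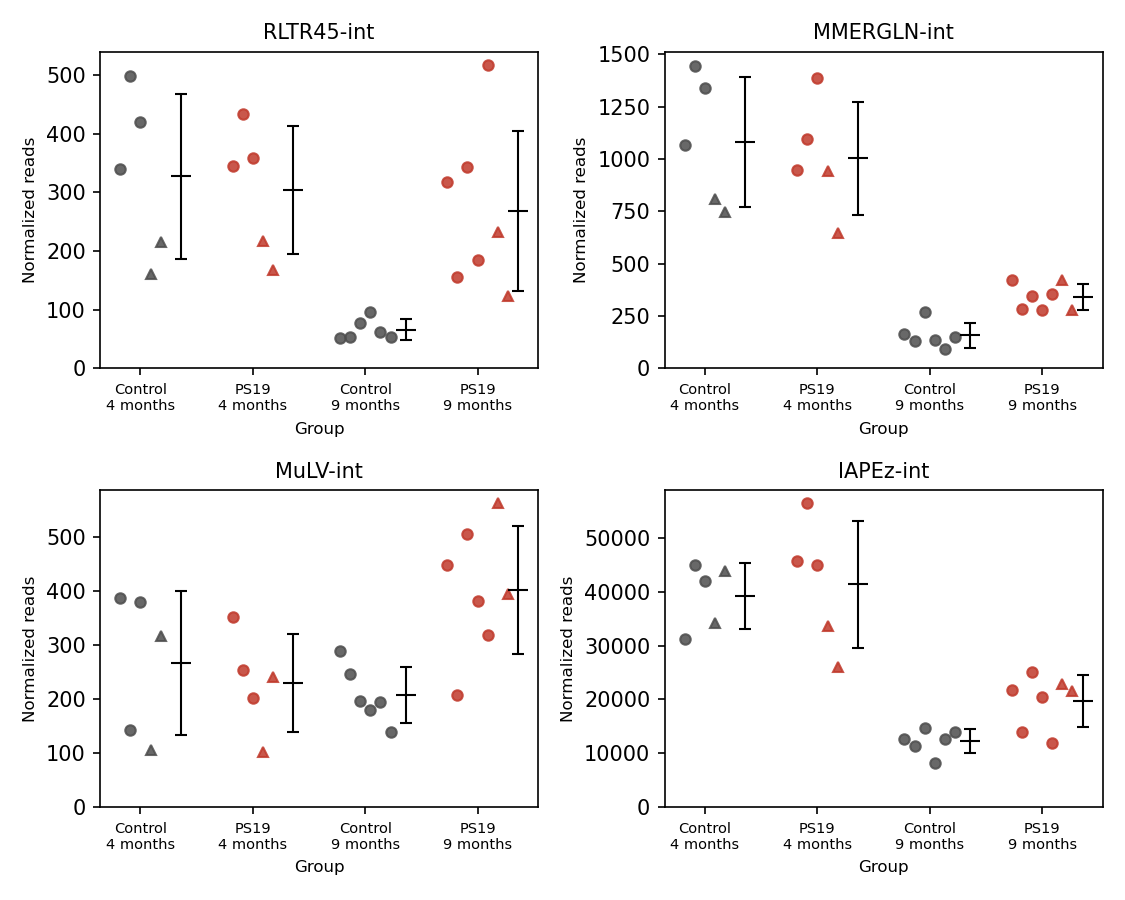
Normalized reads (vertical axis) of RLTR45-int, MMERGLN-int, MuLV-int and IAPEz-int in each sample of the 4 groups, with grey for control, red for PS19, triangles for replicates 4 and 5 at 4 months and PS19 replicates 6 and 7 at 9 months, and bars for mean and SD. At 9 months all 7 PS19 samples lie above every control for RLTR45-int and MMERGLN-int, and 6 and 5 of them do for MuLV-int and IAPEz-int.

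By class, 21 of the 28 higher subfamilies were LTR elements, 5 DNA transposons and 2 LINE elements. LTR elements made up 75% of the higher subfamilies and 59.8% of those tested, which did not differ past the threshold (Fisher's exact test, adjusted p = 0.340). Internal parts of LTR elements made up 10 of the 28 against 111 of the 920 tested (Fisher's exact test, adjusted p = 0.00963), and ERV1 elements 8 against 95 (adjusted p = 0.0288), over 11 groupings of subfamilies that are not independent. In camera, the 111 internal parts stood above the other subfamilies with a preset correlation (adjusted p = 0.00392, median log2 fold change 0.37), and the call was lost with an estimated correlation (adjusted p = 0.968). The 95 ERV1 elements did not stand apart in camera (adjusted p = 0.916 with the preset and 0.968 with an estimated correlation), which placed them slightly below the others, although their median log2 fold change was 0.20. The fry test, which compares a set with no change and not with other subfamilies, gave an adjusted p of 0.169 for a rise of the internal parts and of ERV1 elements, and for changes in either direction 0.0153 and 0.00361. That last result was not particular to these sets. For changes in either direction fry also passed for ERVK elements (adjusted p = 0.0353), all LTR elements (0.0342) and DNA transposons (0.0437). It did not for LINE (0.161) and SINE elements (0.339). These camera and fry tests used the 9-month samples alone. In the fit of all samples, every fry result above was lost. There fry gave an adjusted p of 0.868 for a rise and 0.950 for changes in either direction in each of these sets. Camera in that fit called the internal parts with the preset (adjusted p = 1.78e-05) and not with an estimated correlation (0.984). It did not call ERV1 elements with either (0.726 and 0.984).

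Summed over subfamilies, IAP elements stood at 23547 ± 5536 normalized reads in PS19 (SD, n = 7) and 14890 ± 2538 in control (SD, n = 6), a log2 difference of 0.64 (two-sided exact permutation p = 0.0105, adjusted 0.0627 over 17 sums). The sum of all ERVK elements was 57825 ± 6026 against 47546 ± 4128 (exact p = 0.00816, adjusted 0.0627), and 7 of 7 PS19 animals lay above the control median. As percent of repeat reads, IAP elements were at 5.30 ± 1.32 against 3.69 ± 0.55 (exact p = 0.0262, adjusted 0.140 over 16 shares) and ERVK elements at 12.97 ± 1.20 against 11.78 ± 0.53 (exact p = 0.0519, adjusted 0.190), with 5 of 7 PS19 animals above the control median in each. Other shares were lower in PS19. Satellite repeats were at 1.07 ± 0.07 against 1.19 ± 0.04 (exact p = 0.00816, adjusted 0.131). ERVL elements were at 2.75 ± 0.09 against 2.91 ± 0.11 (exact p = 0.0210, adjusted 0.140). In each of these, 0 of 7 PS19 animals lay above the control median. The lower shares do not show a fall of these repeats. The satellite sum was 4774 ± 409 in PS19 against 4784 ± 216 in control (exact permutation p = 0.923). The ERVL sum was 12288 ± 1037 against 11735 ± 560 (exact permutation p = 0.289). No share passed after adjustment. Total repeat signal was 447548 ± 47923 against 403806 ± 31118 (exact p = 0.0693, adjusted 0.196). None of the 17 sums passed after adjustment. At 4 months, the IAP sum was at 49697 ± 14128 in PS19 and 47737 ± 7124 in control (SD, n = 5 each), a log2 difference of 0.02 (exact p = 0.833), with 0.28 in replicates 1 to 3 and -0.36 in replicates 4 and 5. The ERVK sum differed by -0.09 at that age (exact p = 0.810).

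At 4 months, the same comparison gave 0 subfamilies with limma, edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in each of these. Chance alone gives about 5 percent of the tested subfamilies, so the lack of calls is no evidence that there was no effect. RLTR45-int stood at 304 ± 109 in PS19 and 327 ± 140 in control (SD, n = 5 each), a log2 fold change of -0.07 (SE 0.40). MMERGLN-int stood at 1004 ± 270 and 1081 ± 312. With a term for the sets of 4-month samples, fitted to that age alone, 0 subfamilies passed. In that fit 5 had an unadjusted p under 0.05, again fewer than chance alone gives. On simulated reads, that fit recovered 68.8% of 2-fold and 34.4% of 1.5-fold changes, whereas the fit of all samples recovered 3.12% and 0%. The simulated reads left out the spread within the sets of real 4-month samples, so recovery may be overstated. The 0 calls with the set term thus do not show that changes of these sizes were absent.

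Whether the PS19 effect differed between ages was tested as an interaction. In limma 0 subfamilies passed, with 8 at an unadjusted p under 0.05. In edgeR 0 passed with 11 at that level, and in DESeq2 1 passed with 14. Each of these counts was under the 5 percent of tested subfamilies that chance alone gives. The lack of calls is thus no evidence of equal effects at the 2 ages. The DESeq2 call was RLTR45-int, and with the term for the 4-month sets limma called RLTR45-int and MMERGLN-int. Across the 920 subfamilies, which are not independent replicates, log2 fold changes at 9 and 4 months had a Pearson correlation of 0.0719 and a Spearman correlation of 0.0763. Of the 28 higher at 9 months, 8 had a positive log2 fold change at 4 months, where 37.0% of all 920 were positive.

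Between ages, most subfamilies had lower values at 9 months. In control animals 730 were lower and 56 higher, and in PS19 animals 708 were lower and 56 higher (limma). With only replicates 4 and 5 of the 4-month samples, 462 were lower and 150 higher in control, and 462 and 129 in PS19, and the median log2 fold change went from -2.14 to -0.96 in control and from -1.83 to -0.95 in PS19. MERVL-int was lower at 9 months in both genotypes, with a log2 fold change of -3.22 in control and -2.55 in PS19. MMERGLN-int, ERVB4_1-I_MM-int (-3.49) and MTE2a-int (-3.83) were the others named in control, MMERGLN-int at -2.80. MMERVK10C-int (-3.13), ERVB4_2-I_MM-int (-2.49) and MLT2B4 (-2.28) were the others named in PS19. MER50B (10.09), LTR81 (6.19), LTR104_Mam (5.90) and L1MEi (5.92) were higher at 9 months in control, and the same 4 led in PS19. Scaled within repeats, 287 were higher and 311 lower in control, and 285 and 285 in PS19, and the named subfamilies kept their direction and passed. The falls shrank under that scaling. In control MMERGLN-int went to -0.82, ERVB4_1-I_MM-int to -1.56, MERVL-int to -1.24 and MTE2a-int to -1.92, and in PS19 MMERVK10C-int to -1.41, ERVB4_2-I_MM-int to -0.77, MLT2B4 to -0.56 and MERVL-int to -0.82. The rises grew, MER50B to 11.70 in control. Age coincides with any difference in preparation or scaling between the 2 ages, so these cannot be told apart.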

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

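The tests of explanations in this part were chosen after the patterns were seen, apart from the counts of other splits at 9 months and between ages. The interaction test of named subfamilies was added after the values were seen, on subfamilies selected for their 9-month effect, which favors a difference.

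In control replicate 3 at 9 months, total repeat signal was 462762 normalized reads, far from the other 5 controls at 370990 to 405167. RLTR16C_MM was at 12.6 in the same sample and at 3.02 to 5.69 in the other controls. Of 60 groups of values examined, 2 had such a sample, and chance gives about 1 in 20. The PS19 effect at 9 months minus that at 4 months was 1.96 (log2) for RLTR45-int and 1.27 for MMERGLN-int (permutation adjusted p = 0.0331 for both, over 13 subfamilies).

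The 28 subfamilies higher in PS19 at 9 months, of which 21 are LTR elements, were weighed against library make-up and animal order. After scaling within repeats, 8 of the 28 still passed, which argues against a larger repeat share as the whole cause for those 8; for the other 20 the median log2 fold change went from 0.65 to 0.47 and a larger repeat share stays open. With the lower-numbered PS19 animals left out, 6 subfamilies passed, which argues against those animals as the only source for these 6; for the other calls it stays open, because the 28 subfamilies chosen anew from PS19 replicates 1 to 5 and 3 controls, the 6 excluded, were 0.29 above all subfamilies in replicates 6 and 7 (0.18 to 0.41 over 20 divisions of the controls), the highest of the 28 pairs among those 2 animals and the 6 controls, with the next at 0.18, but included called ones for 46.4% only. The background that separates the 4-month samples stays open. The 28 differed by a median of 1.60 between those sets (bootstrap interval 1.30 to 2.08) against 1.93 for all subfamilies. The bootstrap drew subfamilies, not animals, so its interval leaves out the spread between animals. Across all subfamilies the 9-month effect and the set difference had a Pearson correlation of -0.0122. A constantly active RLTR45-int copy linked to the transgene stays open too, since it would need a log2 fold change of 0.69 at 4 months if both ages share a scale, against an upper bound of 0.76 with all samples and of 0.46 with the set term added after seeing the data, and so does a change that comes with age in PS19.

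The division of the 4-month samples was weighed against scaling and background. A wrong scaling factor per library would move all subfamilies alike, whereas 66 of 593 well-measured subfamilies differed by under 0.5 of the median difference. A few abundant subfamilies are argued against by the 914 of 920 that were higher. Reads from introns or genomic DNA may account for it, since DNA transposons, which have no active copies in mouse, differed by 1.36 more on the log2 scale than IAP elements (bootstrap interval 1.04 to 1.73). That interval also comes from drawing subfamilies, which are not independent, and does not measure the spread between animals. No biological explanation was tested, as the sets held both genotypes.

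Against the general fall, 9 subfamilies with a mean of at least 50 in the 9-month samples were over 8 times higher at 9 months, led by MER50B at 2902 ± 397 (SD, n = 13) against 2.28 ± 3.11 (SD, n = 10). In all 9 of 9, every 9-month sample lay above every 4-month sample. Reads of the 2 ages counted differently and a change with age cannot be told apart here, because any difference in preparation or counting between the ages would coincide with age.

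Other splits of the same samples, 100 per comparison, were counted. At 9 months, 2 of the 100 splits, the real one included, gave as many calls as the real 1 with all samples, the highest other giving 1. This is a share under 0.05, but counts of 1 against 1 cannot exclude chance. In the 9-month samples alone, 2, the real one included, gave as many as the real 31, again a share under 0.05. The highest other split gave 251, far above the real count, so chance is not excluded there either. What that split follows was not tested. At 4 months and for the interaction, all 100 splits gave at least the real 0, which no split can fail to reach, so nothing follows from this on chance. The highest other counts, 854 and 795, came from splits that put 5 of the 6 replicates 1 to 3 at 4 months into the control role, which follows the sets of high and low signal. Between ages, 1 split, the real one, gave 786 calls in control and 764 in PS19, with highest others of 731 and 628, so chance alone is unlikely at the 0.05 level.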

How the results depend on the processing

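Of the alternatives, the term for the 4-month sets, the subsets of animals, and the repeated settings in the 9-month samples alone were chosen after seeing the data; the Xist covariate, gene lists and gene positions were not run. The cause was not tested unless fewer samples or subfamilies show it. At 9 months the count of 1 became 2 with no filter and with DESeq2, 13 with quantile scaling (10 higher, 3 lower), 17 with TMM (14 higher, 3 lower), 108 with sample weights, 31 in the separate fit per age, and 22 with the set term; leaving out each sample gave 1 to 2, the 2 without control replicate 3. In the 9-month samples alone, 31 became 8 with no filter (8 higher, 0 lower), 20 with quantile scaling (10 higher, 10 lower), 15 with TMM (8 higher, 7 lower), 91 with sample weights, 6 with no trend (6 higher, 0 lower), 6 at a threshold of 0.01 and 6 with PS19 replicates 6 and 7 only. Leaving out each sample gave 7 to 78: PS19 replicates 1 to 6 gave 19, 18, 18, 52, 11 and 10, and control replicates 1 to 6 gave 13, 11, 78, 7, 12 and 14. At 4 months, 0 became 350 with sample weights and 1 with replicates 1 to 3 alone; without each sample it was 0 throughout. For the interaction, 0 became 418 with sample weights, 1 with DESeq2 (1 higher, 0 lower), 2 with the set term (2 higher, 0 lower), 1 with only 4-month replicates 4 and 5 (0 higher, 1 lower), and 3 with only replicates 1 to 3 (3 higher, 0 lower). The sample weights of the fits of all samples did not converge, so their counts say nothing about stability. The correlation of effects, 0.0719, was 0.0484 at a filter of 50, 0.111 with edgeR, and 0.0490 to 0.0920 without each sample. The total age counts stayed within 1.5 times, at 749 to 819 in control and 706 to 790 in PS19 without each sample, but not their split: the 56 higher in control became 139 with the set term, 150 with only 4-month replicates 4 and 5, 233 with quantile scaling and 287 with TMM, and the 56 in PS19 became 158, 129, 225 and 285. No named 9-month effect changed direction in 338 values of the 9-month fit, 72 of which missed the threshold. These subfamilies were chosen for their effect in the same animals, so a change of direction was unlikely from the start. RLTR45-int stayed between 1.71 and 2.05 without each sample, and was lower, at 1.38, with PS19 replicates 6 and 7 only.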
